A study of Homo sapiens with 6 samples.

How the data were processed

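RNA of MCF-7 cells was measured on 6 Affymetrix PrimeView arrays hybridised with biotinylated cRNA: untreated cells, cells given Neocarzinostatin (NCS) for 24 h and cells given the NCS-aptamer conjugate for 24 h, 2 arrays each. The deposited values are log2 values that the authors made with RMA, per the labels, which give no version. The log base is not stated there and was taken as 2, the base in which RMA writes its values; with another base the fold changes would scale together. In the deposited table each of the 49395 probe sets has a median over the 6 arrays within 1e-06 of 0, so each was centred on its own median. This step is read from the values and is not described. Centring leaves the differences between arrays as they were, but the table holds no signal level, no background and no detection call. Whether a gene was expressed, and how far above background, is therefore unknown, and a dim probe set could not be told from a bright one.

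The table held 102 control probe sets, 44988 probe sets with 1 gene symbol in the platform annotation, 1832 with several and 2473 with none. Only those with 1 symbol were tested. Of these, 44961 had a gene ID found in the RefSeq gene table (GRCh38.p14, used for names alone), and 0 symbols were updated. They gave 18132 genes, with a median of 2 probe sets each and 11734 genes with more than 1. A gene's value is the mean of its probe sets. The rule set before the data were examined, the probe set with the highest mean level, has no meaning on centred values. The mean had been planned as its alternative and took its place. The probe sets of 1 gene were called in both directions for 101, 34 and 52 genes in the 3 comparisons.

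Genes were compared with limma 3.58.1 in R 4.3.3: lmFit with a coefficient per group over all 6 arrays (3 residual degrees of freedom), contrasts, and eBayes without trend (prior degrees of freedom 6.10, prior SD 0.0995 log2). The contrasts were NCS against untreated, conjugate against untreated and conjugate against NCS. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison are named as called. The 3 groups of 2 arrays share an estimate of spread, and no filter on signal was used. With 2 arrays per group the median standard error of a log2 fold change was 0.098, and the number of arrays limits precision. Same-numbered replicates were not treated as pairs, since their deviations from their group means correlated at -0.034, 0.043 and -0.091 between groups. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

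The comparisons, tests, naming rule, 25 gene lists and most alternatives were set before the data were examined. The lists held 745 members, of which 690 were measured. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry. The markers of other cells comprised 16 measured fibroblast, 17 leukocyte and 12 endothelial genes, of which 1, 0 and 0 also stand in another list. How many of them MCF-7 cells express could not be read from centred values. The genes named were EPCAM, CDKN1A, MDM2 and another, whatever their values. Added to these were the 10 highest and 10 lowest called genes of each comparison whose arrays did not overlap between groups, and up to 4 called genes of each list. Members called against the direction of a called list, where 5 or fewer, were chosen after their values were seen. So were genes in which 1 treatment was called apart from both other groups.

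The gene and list tests were tested on simulated data with the spread found here, 100 genes changed 1.5-fold and 100 changed 2-fold in each comparison, with both directions in equal number. At 1.5-fold 59, 64 and 61% were recovered in the 3 comparisons and at 2-fold 99% in each. False calls made up 9.60, 5.14 and 2.99% of all calls. A list shifted on purpose was called each time, and 0 other lists were. The simulated genes were drawn independently, so false list calls that come from correlation between genes could not appear there.

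Control probe sets were read per array: the 5' and 3' sets of GAPDH and ACTB, the Alu and rRNA sets, the background sets graded by GC count, and the 18 sets of RNAs added before hybridisation. Alternatives to the choices above were other ways to join probe sets, quantile normalization, median centring, scaling on the hybridisation controls, robust eBayes, array weights, fits of 2 groups alone, a replicate term, other thresholds, other list tests and leaving out each array in turn. Filters on dim probe sets and eBayes with a trend in signal level were planned and left out, because both need levels that centred values lack. No dose is given for either treatment, and none was assumed.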

Results

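The transcriptomes of MCF-7 cells, an estrogen receptor-positive human breast cancer line of luminal type, were measured on 6 Affymetrix PrimeView arrays. Untreated cells, cells given Neocarzinostatin (NCS), and cells given NCS joined by a Sulfo-LC-SPDP cross linker to an aptamer against EpCAM had 2 arrays each. Both treatments lasted 24 h. NCS is an enediyne antibiotic that cuts DNA, EpCAM is an adhesion protein on the surface of epithelial cells, and an aptamer is a folded nucleic acid that binds a chosen protein. The labels give no dose for either treatment, so it is unknown whether free and conjugated NCS were equal in amount. The deposited table held 49395 probe sets, of which those with a single gene symbol gave values for 18132 genes. The deposited values are centred on each probe set's median, so they show differences between arrays and no expression level. Nothing in the labels says that the 2 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical only, and the number of arrays limits the precision.

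The groups were farther apart than their replicates. The first principal component over all genes (56.9% of the variance) placed the untreated arrays at -25.9 and -25.8, the conjugate arrays at 4.82 and 4.66 and the NCS arrays at 19.4 and 22.8. The second component (23.9%) held the conjugate arrays at -16.6 and -18.5 and the NCS arrays at 12.6 and 10.4. The log2 difference between the replicates of a group had an SD across genes of 0.15 for untreated cells, 0.18 for NCS and 0.18 for the conjugate.

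Control probe sets differed between groups as well. The 5' minus 3' difference of the GAPDH control, which falls when RNA is broken or copied incompletely, was 0.30 and 0.21 in the untreated arrays, -0.26 and -0.30 in the NCS arrays and 0.14 and 0.024 in the conjugate arrays (log2, centred). The same difference of the ACTB control was 0.96 and 0.53 in untreated, -0.13 and -0.60 in NCS and 0.064 and -0.13 in conjugate arrays. The control for Alu repeats stood at 0.35 and 0.34 in the NCS arrays against 0.10 and -0.10 in untreated and -0.12 and -0.10 in conjugate arrays. The 5' control of 28S rRNA was -0.96 and -0.89 in untreated, 0.78 and 0.64 in NCS and 0.087 and -0.087 in conjugate arrays, while its 3' control lay between -0.10 and 0.20 in all 6. The 3' control of 18S rRNA was 0.55 and 0.48 in the NCS arrays, 0.10 and -0.10 in untreated and -0.10 and -0.30 in conjugate arrays. The median of the 18 hybridisation controls, RNAs added in fixed amounts, was -0.22 and -0.31 in untreated, 0.064 and 0.035 in NCS and -0.0073 and 0.46 in conjugate arrays. If arrays are scaled on these controls, the median log2 fold change of all genes moves from 0.039 to -0.28 for NCS against untreated cells, from 0.034 to -0.46 for the conjugate against untreated cells and from 0.0043 to -0.17 for the conjugate against NCS. Directions given here are therefore relative to the other genes on the array.

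**Figure D1:**
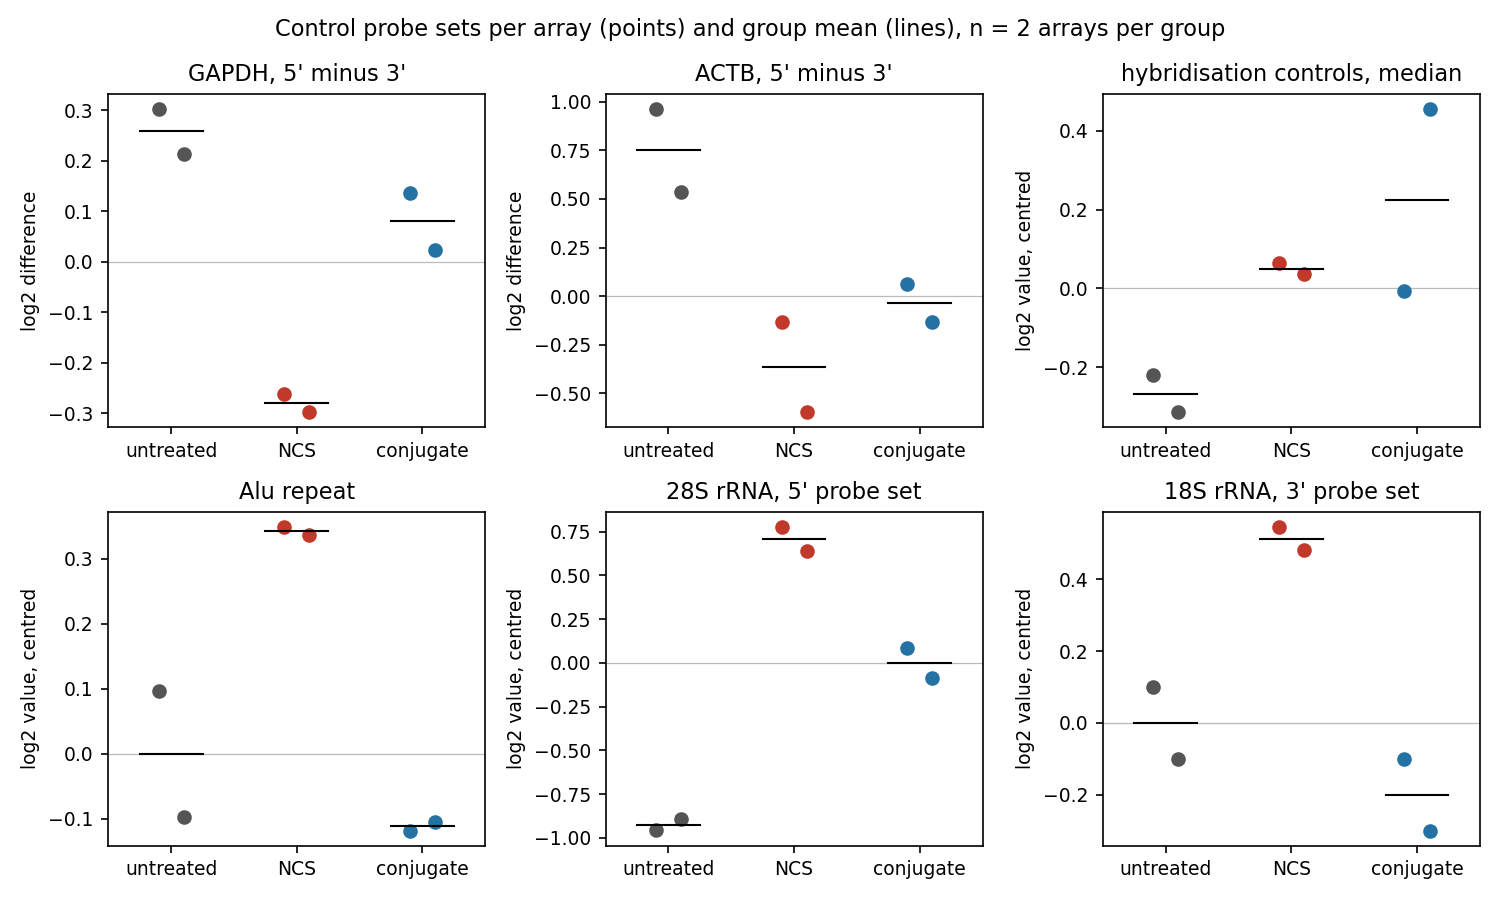
Control probe sets per array: each panel shows one control, the vertical axis is a centred log2 value or a 5' minus 3' log2 difference, points are arrays and lines are the means of 2 arrays. Both NCS arrays lie below the other 4 in the GAPDH difference and above them in the Alu, 28S 5' and 18S 3' controls, and the conjugate's hybridisation controls are -0.0073 and 0.46.

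The first comparison asks what free NCS changed in the cells. Camera with a preset correlation called lists of S phase and p53 target genes higher relative to other genes, and lists of G2/M, NRF2, hypoxia and glycolysis, ATF4, heat shock, immediate early and oxidative phosphorylation genes lower, but 0 of these 10 list calls held with an estimated correlation, where 6 of 25 lists passed an unadjusted p under 0.05 and the lowest adjusted p = 0.192. The median of the p53 apoptosis targets also fell below 0 under scaling on the hybridisation controls. Camera with the preset correlation still called all 10 lists there, but it ranks a list against other genes. An equal shift of every gene bears little on that ranking, so these calls are no check on the scaling. Among single genes, PIDD1 (1.96 ± 0.09), which codes for a p53-induced death domain protein, had one of the largest rises (log2 fold change ± standard error, 2 arrays per group). In all, limma called 2118 genes higher and 2476 lower of 18132 at an adjusted p under 0.05, of which 122 and 257 changed at least 2-fold.

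In the list of S phase and replication genes, 33 of 43 measured members were called higher and 1 lower (36 and 1 when adjusted over the list alone). The S phase list had camera adjusted p = 1.35e-14, and adjusted p = 0.192 with an estimated correlation. The largest rises among them were those of POLE (1.39 ± 0.12), a replicative DNA polymerase subunit, E2F8 (1.33 ± 0.11), an E2F family transcription factor, MCM10 (1.21 ± 0.09), a factor of replication initiation, and LIG1 (1.20 ± 0.09), the ligase that joins Okazaki fragments. The exception, chosen after its values were seen, was RRM1 (-0.50 ± 0.10), the large subunit of ribonucleotide reductase. Scaling on the hybridisation controls left 8 higher and 1 lower with a list median of 0.24, against a median of 0.56 in the deposited values. In the list of G2/M and mitosis genes, 3 of 39 measured members were called higher and 26 lower (3 and 27 when adjusted over the list alone). The G2/M list had camera adjusted p = 4.31e-11, and adjusted p = 0.192 with an estimated correlation, at a median of -0.46. Among the falls were HMMR (-2.18 ± 0.09), a microtubule-associated hyaluronan receptor, CENPA (-1.69 ± 0.10), the histone of centromeres, CENPE (-1.38 ± 0.17), a kinetochore motor, and AURKA (-1.37 ± 0.08), a kinase of the spindle poles. Members called higher, named after their values were seen, were AURKB (0.58 ± 0.09), FOXM1 (0.47 ± 0.11) and NUSAP1 (0.46 ± 0.09). Scaling on the hybridisation controls left 0 members of this list higher and 26 lower. The G2/M genes called lower are lower in arrays in which the GAPDH 5' minus 3' control averaged -0.28, against 0.26 in untreated arrays. Calls that ended when an array was left out, with the adjusted p then found, were those of RRM1 (0.0512) without untreated 1, FOXM1 (0.0655 to 0.104) without untreated 1, untreated 2 or NCS 1.

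Among p53 targets of cell cycle arrest and feedback, 16 of 31 measured members were called higher and 3 lower (16 and 3 when adjusted over the list alone). The arrest and feedback list had camera adjusted p = 0.00194, and adjusted p = 0.192 with an estimated correlation. Scaling on the hybridisation controls left 3 higher and 3 lower with a list median of 0.054, against a median of 0.37 in the deposited values. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.81 ± 0.09 and MDM2, the ubiquitin ligase that removes p53, by 0.74 ± 0.10. Both lost their calls under that scaling (0.49, adjusted p = 0.131, for CDKN1A and 0.42, adjusted p = 0.217, for MDM2). Larger rises were those of SUSD6 (1.08 ± 0.12), XPC (1.06 ± 0.10), a damage sensor of nucleotide excision repair, and PHLDA3 (1.05 ± 0.09), an inhibitor of AKT. Members that fell were FUCA1 (-0.99 ± 0.11), a lysosomal fucosidase, and, named after their values were seen, the atypical cyclins CCNG1 (-0.84 ± 0.11) and CCNG2 (-0.57 ± 0.09). Among p53 targets of apoptosis, 7 of 17 measured members were called higher and 1 lower (7 and 1 when adjusted over the list alone). The apoptosis list had camera adjusted p = 0.010, and adjusted p = 0.327 with an estimated correlation. The median of these apoptosis targets was 0.15 in the deposited values and -0.17 under scaling on the hybridisation controls, 0.11 above that of all genes, with 3 members called higher and 1 lower. Next to PIDD1, the TRAIL receptor genes TNFRSF10A (1.10 ± 0.11) and TNFRSF10D (1.19 ± 0.09) and BBC3 (0.84 ± 0.11), which codes for the BH3-only protein PUMA, rose. PMAIP1 (-0.39 ± 0.09), the gene of the BH3-only protein NOXA, fell and is named after its value was seen. EPCAM, the gene of the conjugate's target, stood at 0.24 ± 0.09, adjusted p = 0.0812, without a call, and at -0.080 under scaling on the hybridisation controls. Another gene of the naming rule had no named probe set here. Leaving out 1 array ended the call of PMAIP1 (0.0503 to 0.0845) without untreated 1, untreated 2 or NCS 1.

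In the NRF2 and oxidative stress list, 0 of 27 measured members were called higher and 16 lower (0 and 17 when adjusted over the list alone). The NRF2 list had camera adjusted p = 7.07e-07, and adjusted p = 0.192 with an estimated correlation. The members called lower included MT1X (-1.71 ± 0.19), a metal-binding metallothionein, ME1 (-1.43 ± 0.11), the cytosolic malic enzyme, SLC7A11 (-0.97 ± 0.09), the cystine transporter, and TXNRD1 (-0.97 ± 0.12), thioredoxin reductase. Of the hypoxia and glycolysis genes, 1 of 27 measured members was called higher and 11 lower (2 and 12 when adjusted over the list alone). The hypoxia and glycolysis list had camera adjusted p = 8.50e-05, and adjusted p = 0.192 with an estimated correlation. The list included PGK1 (-1.49 ± 0.08), a glycolytic kinase, P4HA1 (-1.10 ± 0.11), a prolyl hydroxylase of collagen, and KDM3A (-1.07 ± 0.09), a histone demethylase. The neuronal enolase gene ENO2 (0.95 ± 0.20) was higher, against that list's direction. For the ATF4 and unfolded protein response list, 2 of 29 measured members were called higher and 11 lower (3 and 11 when adjusted over the list alone). The ATF4 list had camera adjusted p = 0.010, and adjusted p = 0.192 with an estimated correlation. Its largest falls were those of DDIT4 (-1.89 ± 0.08), an inhibitor of mTORC1, ASNS (-1.16 ± 0.09), asparagine synthetase, and VLDLR (-1.06 ± 0.15), a lipoprotein receptor. Against its direction, and chosen after their values were seen, were SEL1L (0.40 ± 0.09) and SLC7A5 (0.26 ± 0.08); SLC7A5 stood at -0.054 under scaling on the hybridisation controls. With 1 array left out, calls were lost for ENO2 (0.0625 to 0.0819) without untreated 1 or NCS 1, SEL1L (0.0613 to 0.0929) without untreated 2 or NCS 2, SLC7A5 (0.0601 to 0.207) without any 1 of the 6 arrays.

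Of the heat shock genes, 1 of 19 measured members was called higher and 10 lower (1 and 11 when adjusted over the list alone). The heat shock list had camera adjusted p = 0.00647, and adjusted p = 0.327 with an estimated correlation. Examples are HSPH1 (-0.67 ± 0.10), a large chaperone of the cytosol, HSPE1 (-0.62 ± 0.09), a mitochondrial co-chaperone, and HSP90AA1 (-0.59 ± 0.11), the inducible HSP90. Higher was HSPB8 (0.53 ± 0.10), a small heat shock protein gene named after its value was seen. Among immediate early and AP-1 genes, 1 of 29 measured members was called higher and 12 lower (1 and 12 when adjusted over the list alone). The AP-1 list had camera adjusted p = 0.010, and adjusted p = 0.192 with an estimated correlation. These included CCN2 (-2.45 ± 0.10), a matrix-associated growth factor, MYC (-1.36 ± 0.11), CCN1 (-1.28 ± 0.10) and FOS (-1.24 ± 0.15). The nuclear receptor gene NR4A1 (0.50 ± 0.09), again named after its value was seen, was higher. Of the nuclear-coded oxidative phosphorylation genes, 5 of 45 measured members were called higher and 15 lower (6 and 16 when adjusted over the list alone). The oxidative phosphorylation list had camera adjusted p = 0.020, and adjusted p = 0.509 with an estimated correlation. The lowest were NDUFV2 (-0.999 ± 0.09), COX5B (-0.78 ± 0.10), ATP5F1A (-0.77 ± 0.10) and SDHD (-0.77 ± 0.08), subunits of complexes I, IV, V and II. Those called higher, named after their values were seen, were NDUFA9 (0.45 ± 0.10), COX8A (0.44 ± 0.09), NDUFV1 (0.31 ± 0.08), SDHA (0.30 ± 0.09) and COX7B (0.28 ± 0.09). The last 3 stood at -0.0024, -0.017 and -0.040 under scaling on the hybridisation controls, which left 0 members of the list called higher and 15 lower. Without probe sets that can match several genes, the calls of heat shock (adjusted p = 0.126), hypoxia (adjusted p = 0.0555) and oxidative phosphorylation (adjusted p = 0.115) ended. The oxidative phosphorylation call also ended without untreated 2 (adjusted p = 0.106) and without NCS 2 (adjusted p = 0.0526). The NRF2 and oxidative phosphorylation members called lower are lower in arrays in which the Alu control averaged 0.34 and the ACTB 5' minus 3' control -0.36, against 0.75 for ACTB in untreated arrays. The following calls ended without 1 array, at the adjusted p in brackets: HSPB8 (0.0588) and COX8A (0.0677) without untreated 1, NDUFA9 (0.0526 to 0.0975) without untreated 1 or NCS 2, NDUFV1 (0.0601 to 0.132), SDHA (0.0585 to 0.191) and COX7B (0.116 to 0.166) without untreated 1, untreated 2, NCS 1 or NCS 2.

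The other 15 lists were not called by camera. Of 10 apoptosis inhibitors, 1 was called higher and 3 lower (adjusted p = 0.247). Of 45 replication-dependent histone genes, 1 was called higher and 6 lower, 0 and 5 adjusted over the list alone (adjusted p = 0.0502). Of 31 DNA double-strand break repair genes, 6 were called higher and 6 lower, 7 and 6 adjusted over the list alone (adjusted p = 0.674). Of 27 estrogen receptor targets, 4 were called higher and 2 lower (adjusted p = 0.674). Of 23 NF-kB and inflammatory genes, 2 were called higher and 2 lower (adjusted p = 0.366). Of 37 interferon response genes, 8 were called higher and 0 lower, 6 and 0 adjusted over the list alone (adjusted p = 0.0555). Of 19 cholesterol synthesis genes, 6 were called higher and 3 lower (adjusted p = 0.569). Of 47 cytosolic ribosomal protein genes, 0 were called higher and 1 lower, 0 and 0 adjusted over the list alone (adjusted p = 0.785). Of 27 luminal epithelial genes, 0 were called higher and 6 lower (adjusted p = 0.291). Of 24 basal and mesenchymal genes, 2 were called higher and 5 lower, 3 and 5 adjusted over the list alone (adjusted p = 0.677). Of 18 EpCAM signalling and stemness genes, 2 were called higher and 4 lower (adjusted p = 0.426). Of 31 lysosome and autophagy genes, 5 were called higher and 11 lower (adjusted p = 0.114). Of 16 fibroblast markers, 1 was called higher and 1 lower (adjusted p = 0.366). Of 17 leukocyte markers, 0 were called higher and 0 lower (adjusted p = 0.653). Of 12 endothelial markers, 1 was called higher and 0 lower (adjusted p = 0.208). Within these lists, ISG15 (1.40 ± 0.15), an interferon-induced ubiquitin-like protein gene, and IFIT2 (0.87 ± 0.12), an interferon-induced RNA-binding protein gene, were higher. Under scaling on the hybridisation controls 0 of the DNA double-strand break repair genes were called higher and 7 lower. In the deposited values these genes changed in both directions: EXO1 (0.82 ± 0.10), RAD54L (0.80 ± 0.08) and BLM (0.72 ± 0.12) were higher and XRCC4 (-0.87 ± 0.09) was lower. The autophagy genes ATG3 (-1.07 ± 0.09) and ATG5 (-1.02 ± 0.11), the linker histone gene H1-2 (-1.69 ± 0.10) and the pluripotency factor gene KLF4 (-0.78 ± 0.10) were lower as well. The interferon list's call was gained under scaling on the hybridisation controls (adjusted p = 0.034) and without untreated 2 (adjusted p = 0.0323), and the histone list's under median centring (adjusted p = 0.0479) and without untreated 1 (adjusted p = 0.0346) or NCS 2 (adjusted p = 0.0215). Median, mean and test direction differed in sign for the DNA double-strand break repair genes (-0.052, 0.0027, downward), basal and mesenchymal genes (0.048, -0.036, downward) and EpCAM signalling and stemness genes (0.041, -0.13, downward).

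By size among called genes whose arrays did not overlap between groups, the 10 highest changes were those of RIBC2 (2.44 ± 0.25), PIDD1, CGA (1.95 ± 0.18), the alpha subunit of glycoprotein hormones, APOBEC3B (1.94 ± 0.10), a cytidine deaminase acting on DNA, and SHC2 (1.80 ± 0.11), NT5DC2 (1.77 ± 0.16), GPR19 (1.73 ± 0.17), POMZP3 (1.65 ± 0.09), CPNE7 (1.64 ± 0.10) and GPAA1 (1.63 ± 0.15). The 10 lowest were CCN2, TSC22D3 (-2.23 ± 0.11), a glucocorticoid-induced gene, HMMR, KYAT3 (-2.16 ± 0.10) and CYB5R4 (-2.14 ± 0.10), CUL4B (-2.001 ± 0.10), a scaffold of ubiquitin ligases, MMADHC (-1.99 ± 0.09), a factor of vitamin B12 metabolism, DDIT4, IDH1 (-1.86 ± 0.11), the cytosolic isocitrate dehydrogenase, and HIBADH (-1.86 ± 0.13). The count of called genes fell from 4594 to 2796 without untreated 1 and to 2846 without untreated 2. Scaling on the hybridisation controls, which moves every log2 fold change of a comparison by the same amount, gave 169 genes higher and 2673 lower.

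**Figure D2:**
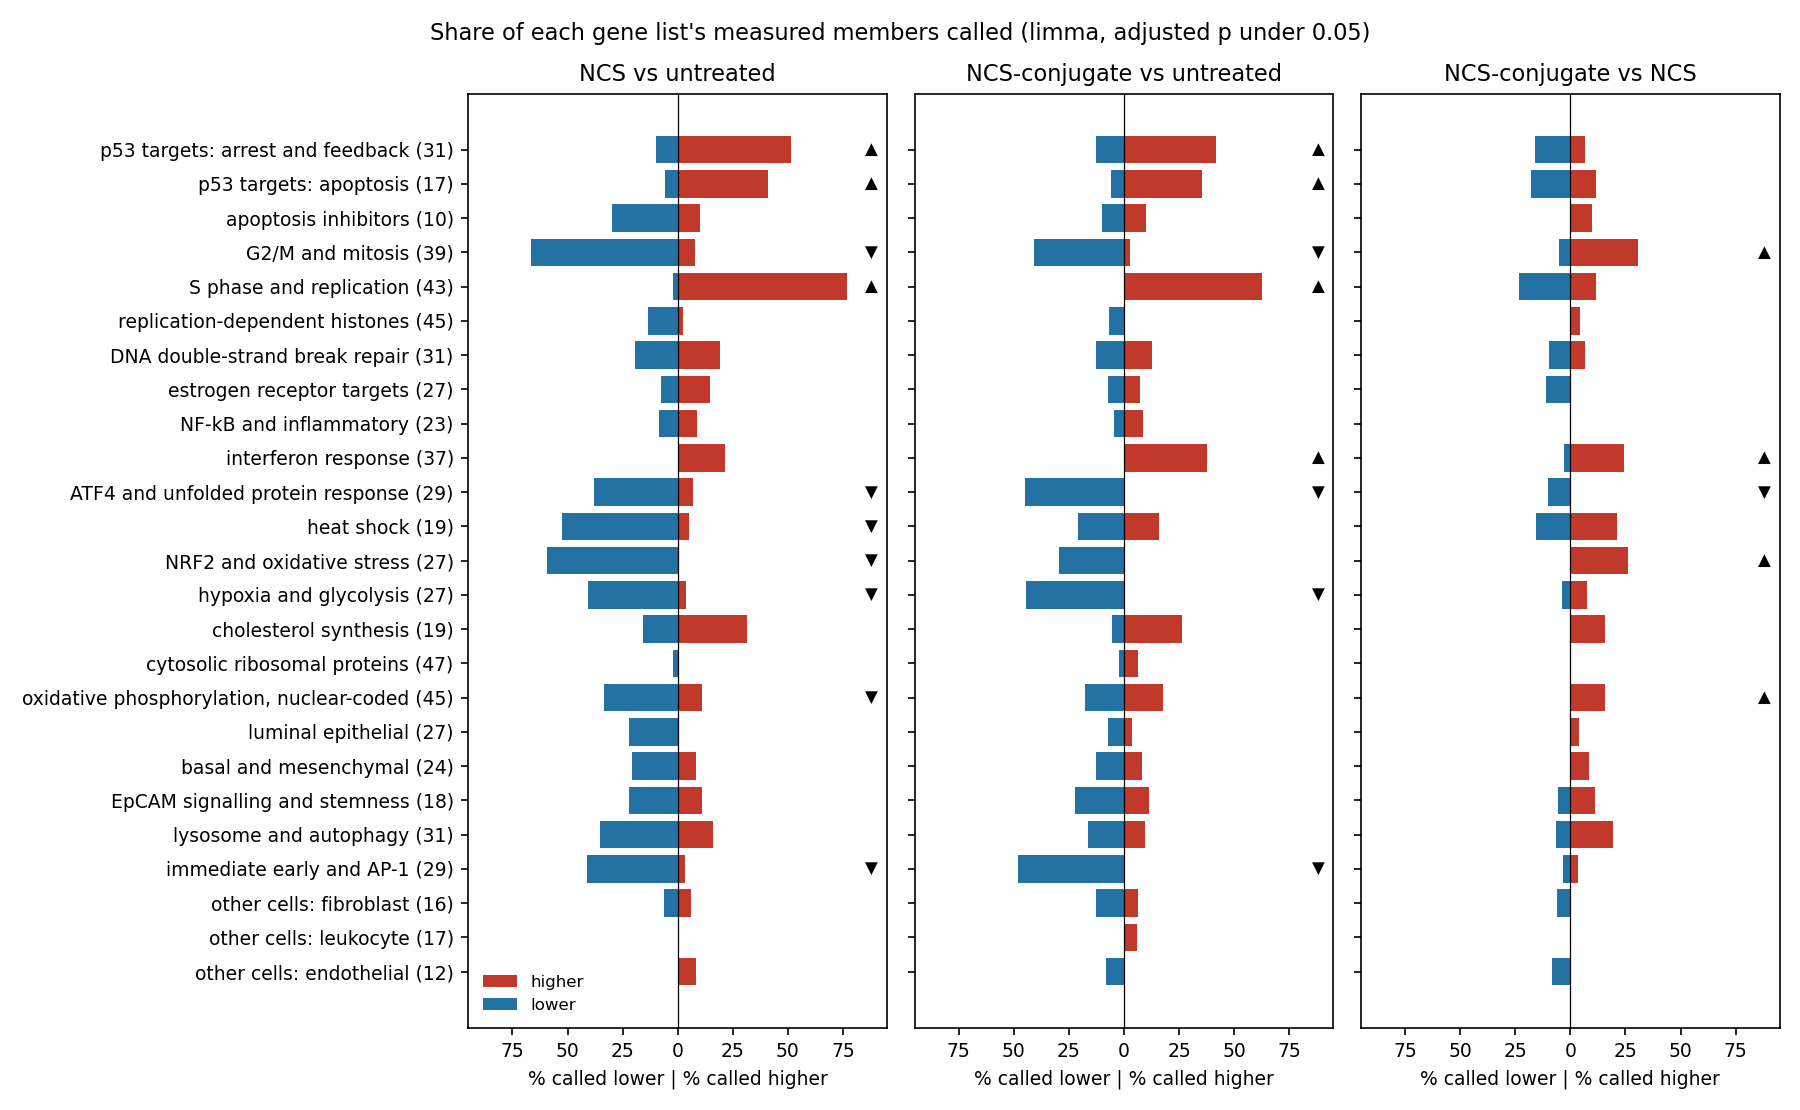
Share of each list's measured members (number in brackets) called higher to the right and lower to the left of 0, in percent, for the 3 comparisons; triangles mark lists called by camera with the preset correlation, pointing in the direction of change relative to other genes. None of these list calls held with an estimated correlation, and under scaling on the hybridisation controls the list medians turned for p53 apoptosis targets in the NCS panel, for interferon and both p53 lists in the conjugate panel, and for interferon, NRF2 and oxidative phosphorylation in the conjugate against NCS panel.

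The next comparison asks what the conjugate changed. Relative to other genes, camera with a preset correlation called replication, interferon and p53 target lists higher and mitotic, ATF4, hypoxia and immediate early lists lower than in untreated cells, but 0 of these 8 list calls held with an estimated correlation, where 5 of 25 lists passed an unadjusted p under 0.05 and the lowest adjusted p = 0.135. The medians of the interferon and both p53 lists also fell below 0 under scaling on the hybridisation controls. Camera with the preset correlation still called all 8 lists there, but its ranking against other genes can hardly respond to an equal shift of every gene. Single interferon genes that rose were ISG15 (2.17 ± 0.15) and IFIT1 (1.39 ± 0.24). The largest falls were those of DDIT4 (-2.56 ± 0.08), TSC22D3 (-2.36 ± 0.11) and SLIT2 (-2.29 ± 0.08), a secreted guidance protein gene. limma called 1206 genes higher and 1804 lower, of which 46 and 116 changed at least 2-fold. EPCAM rose by 0.47 ± 0.09, adjusted p = 0.00682, but its call ended without untreated 2 (adjusted p = 0.0652) and its direction turned under scaling on the hybridisation controls (-0.023).

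In the S phase and replication list, 27 of 43 measured members were called higher and 0 lower (30 and 0 when adjusted over the list alone). The S phase list gave camera adjusted p = 1.20e-16, and adjusted p = 0.181 with an estimated correlation. Examples are E2F8 (1.66 ± 0.11), CCNE2 (1.45 ± 0.15), a cyclin of S phase entry, RRM2 (1.26 ± 0.09), the small subunit of ribonucleotide reductase, and TK1 (1.20 ± 0.09), thymidine kinase. Under scaling on the hybridisation controls the calls were 7 higher and 2 lower with a list median of 0.033, against a median of 0.52 in the deposited values. In the G2/M and mitosis list, 1 of 39 measured members was called higher and 16 lower (3 and 17 when adjusted over the list alone). The G2/M list gave camera adjusted p = 9.37e-07, and adjusted p = 0.251 with an estimated correlation. The lowest were HMMR (-1.75 ± 0.09), CENPE (-1.31 ± 0.17), CENPA (-1.13 ± 0.10) and CENPF (-1.04 ± 0.11). The only member called higher, named after its value was seen, was NUSAP1 (0.57 ± 0.09). The GAPDH 5' minus 3' control averaged 0.080 in the conjugate arrays and the ACTB control -0.035, against 0.26 and 0.75 in untreated arrays. Among p53 targets of arrest and feedback, 13 of 31 measured members were called higher and 4 lower (15 and 5 when adjusted over the list alone). The arrest and feedback list gave camera adjusted p = 0.00127, and adjusted p = 0.226 with an estimated correlation. The median was 0.25 in the deposited values and -0.24 under scaling on the hybridisation controls, 0.22 above that of all genes, with 1 member called higher and 6 lower. TP53I3 (1.12 ± 0.09), a quinone oxidoreductase gene, and SPATA18 (0.78 ± 0.11) and PHLDA3 (0.77 ± 0.09) rose. CDKN1A rose by 0.53 ± 0.09 and MDM2 by 0.37 ± 0.10. Under that scaling CDKN1A stood at 0.036 (adjusted p = 0.883) and MDM2 at -0.13, and the MDM2 call also ended without probe sets that can match several genes (0.23, adjusted p = 0.223). It ended too with the highest-mean probe set (0.14, adjusted p = 0.618), a rule that on centred values picks by the differences between arrays. FUCA1 (-0.87 ± 0.11) and, named after their values were seen, CCNG1 (-0.46 ± 0.11), CCNG2 (-0.42 ± 0.09) and SESN2 (-0.40 ± 0.09) fell. For p53 targets of apoptosis, 6 of 17 measured members were called higher and 1 lower (10 and 1 when adjusted over the list alone). The apoptosis list gave camera adjusted p = 0.000738, and adjusted p = 0.276 with an estimated correlation. Its median was 0.31 in the deposited values and -0.18 under that scaling, 0.27 above that of all genes, with 3 members called higher and 3 lower. PIDD1 (1.27 ± 0.09), TNFRSF10D (1.18 ± 0.09) and BAX (0.57 ± 0.09), a pore-forming protein of mitochondria, rose. PMAIP1 (-0.34 ± 0.09), named after its value was seen, fell. Not every call here held when 1 array was left out, as the adjusted p rose above the threshold for CDKN1A (0.0567) without untreated 1, MDM2 (0.12 to 0.197), CCNG1 (0.0507 to 0.172) and PMAIP1 (0.103 to 0.168) without untreated 1, untreated 2 or conjugate 2, CCNG2 (0.0566 to 0.132) without untreated 1, conjugate 1 or conjugate 2, SESN2 (0.059 to 0.111) without untreated 1, untreated 2, conjugate 1 or conjugate 2.

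In the interferon response list, 14 of 37 measured members were called higher and 0 lower (15 and 0 when adjusted over the list alone). The interferon list gave camera adjusted p = 1.60e-06, and adjusted p = 0.135 with an estimated correlation. The median of the interferon genes was 0.15 in the deposited values and -0.34 under scaling on the hybridisation controls, 0.12 above that of all genes, with 5 members called higher and 4 lower. Besides ISG15 and IFIT1 it included IFIT2 (1.52 ± 0.12) and IFI6 (1.30 ± 0.13). In the ATF4 and unfolded protein response list, 0 of 29 measured members were called higher and 13 lower (1 and 15 when adjusted over the list alone). The ATF4 list gave camera adjusted p = 9.37e-07, and adjusted p = 0.135 with an estimated correlation. Its members included DDIT4, VLDLR (-1.10 ± 0.15), ASNS (-1.04 ± 0.09) and SLC7A11 (-0.999 ± 0.09). Of the hypoxia and glycolysis genes, 0 of 27 measured members were called higher and 12 lower (0 and 15 when adjusted over the list alone). The hypoxia and glycolysis list gave camera adjusted p = 9.37e-07, and adjusted p = 0.135 with an estimated correlation. Lower members were PGK1 (-0.92 ± 0.08), P4HA1 (-0.86 ± 0.11) and PDK1 (-0.84 ± 0.11) and the lactate dehydrogenase gene LDHA (-0.76 ± 0.08). Of the immediate early and AP-1 genes, 0 of 29 measured members were called higher and 14 lower (2 and 14 when adjusted over the list alone). The AP-1 list gave camera adjusted p = 0.000394, and adjusted p = 0.135 with an estimated correlation. The largest falls were those of CCN2 (-1.88 ± 0.10), CCN1 (-1.54 ± 0.10), IER3 (-1.35 ± 0.10) and MYC (-1.13 ± 0.11).

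Camera did not call the other 17 lists. Of 10 apoptosis inhibitors, 1 was called higher and 1 lower (adjusted p = 0.676). Of 45 replication-dependent histone genes, 0 were called higher and 3 lower, 0 and 2 adjusted over the list alone (adjusted p = 0.433). Of 31 DNA double-strand break repair genes, 4 were called higher and 4 lower (adjusted p = 0.425). Of 27 estrogen receptor targets, 2 were called higher and 2 lower (adjusted p = 0.646). Of 23 NF-kB and inflammatory genes, 2 were called higher and 1 lower (adjusted p = 0.188). Of 19 heat shock genes, 3 were called higher and 4 lower, 3 and 7 adjusted over the list alone (adjusted p = 0.051). Of 27 NRF2 and oxidative stress genes, 0 were called higher and 8 lower, 0 and 9 adjusted over the list alone (adjusted p = 0.115). Of 19 cholesterol synthesis genes, 5 were called higher and 1 lower (adjusted p = 0.402). Of 47 cytosolic ribosomal protein genes, 3 were called higher and 1 lower, 2 and 0 adjusted over the list alone (adjusted p = 0.254). Of 45 nuclear-coded oxidative phosphorylation genes, 8 were called higher and 8 lower, 9 and 11 adjusted over the list alone (adjusted p = 0.951). Of 27 luminal epithelial genes, 1 was called higher and 2 lower (adjusted p = 0.217). Of 24 basal and mesenchymal genes, 2 were called higher and 3 lower (adjusted p = 0.646). Of 18 EpCAM signalling and stemness genes, 2 were called higher and 4 lower (adjusted p = 0.40). Of 31 lysosome and autophagy genes, 3 were called higher and 5 lower, 4 and 7 adjusted over the list alone (adjusted p = 0.115). Of 16 fibroblast markers, 1 was called higher and 2 lower (adjusted p = 0.402). Of 17 leukocyte markers, 1 was called higher and 0 lower, 0 and 0 adjusted over the list alone (adjusted p = 0.115). Of 12 endothelial markers, 0 were called higher and 1 lower, 0 and 0 adjusted over the list alone (adjusted p = 0.646). Single members of these lists changed, among them STC2 (-1.41 ± 0.09), a secreted glycoprotein gene, MT1X (-1.84 ± 0.19), HSPA1B (-1.15 ± 0.10), an inducible HSP70 gene with a near-identical copy that its probe set may also read, and the cholesterol pathway genes ACAT2 (0.89 ± 0.08) and FDPS (0.73 ± 0.08). Scaling on the hybridisation controls left 0 cholesterol synthesis genes called higher and 8 lower. The heat shock list was called under scaling on the hybridisation controls (adjusted p = 0.0304) and when untreated 2 (adjusted p = 0.0362) or either NCS array (adjusted p = 0.0305) was left out. The NRF2 list was called under that scaling (adjusted p = 0.0091) and without conjugate 1 (adjusted p = 0.0383). Median, mean and test differed in sign for the apoptosis inhibitors (-0.053, 0.014, downward), replication-dependent histone genes (0.014, -0.037, downward), NRF2 and oxidative stress genes (0.032, -0.18, downward) and nuclear-coded oxidative phosphorylation genes (0.029, 0.0046, downward).

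By size, the 10 highest changes of that kind were those of CGA (2.58 ± 0.18), APOBEC3B (2.49 ± 0.10) and RIBC2 (2.47 ± 0.25), ISG15, KRTAP21-2 (1.91 ± 0.12) and FAM111B (1.75 ± 0.13), E2F8, IFIT2, SERTAD1 (1.45 ± 0.15) and CCNE2. The lowest included TXNIP (-2.09 ± 0.09), a binding partner of thioredoxin, CTH (-1.94 ± 0.12), an enzyme of cysteine synthesis, PCK1 (-1.91 ± 0.09), an enzyme of gluconeogenesis, and SLC33A2 (-1.91 ± 0.16). The 3010 called genes became 1189 without untreated 1, 1467 without untreated 2, 1954 without conjugate 1 and 1840 without conjugate 2. Scaling on the hybridisation controls, which differ between the conjugate arrays themselves, gave 40 genes higher and 6136 lower.

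**Figure D3:**
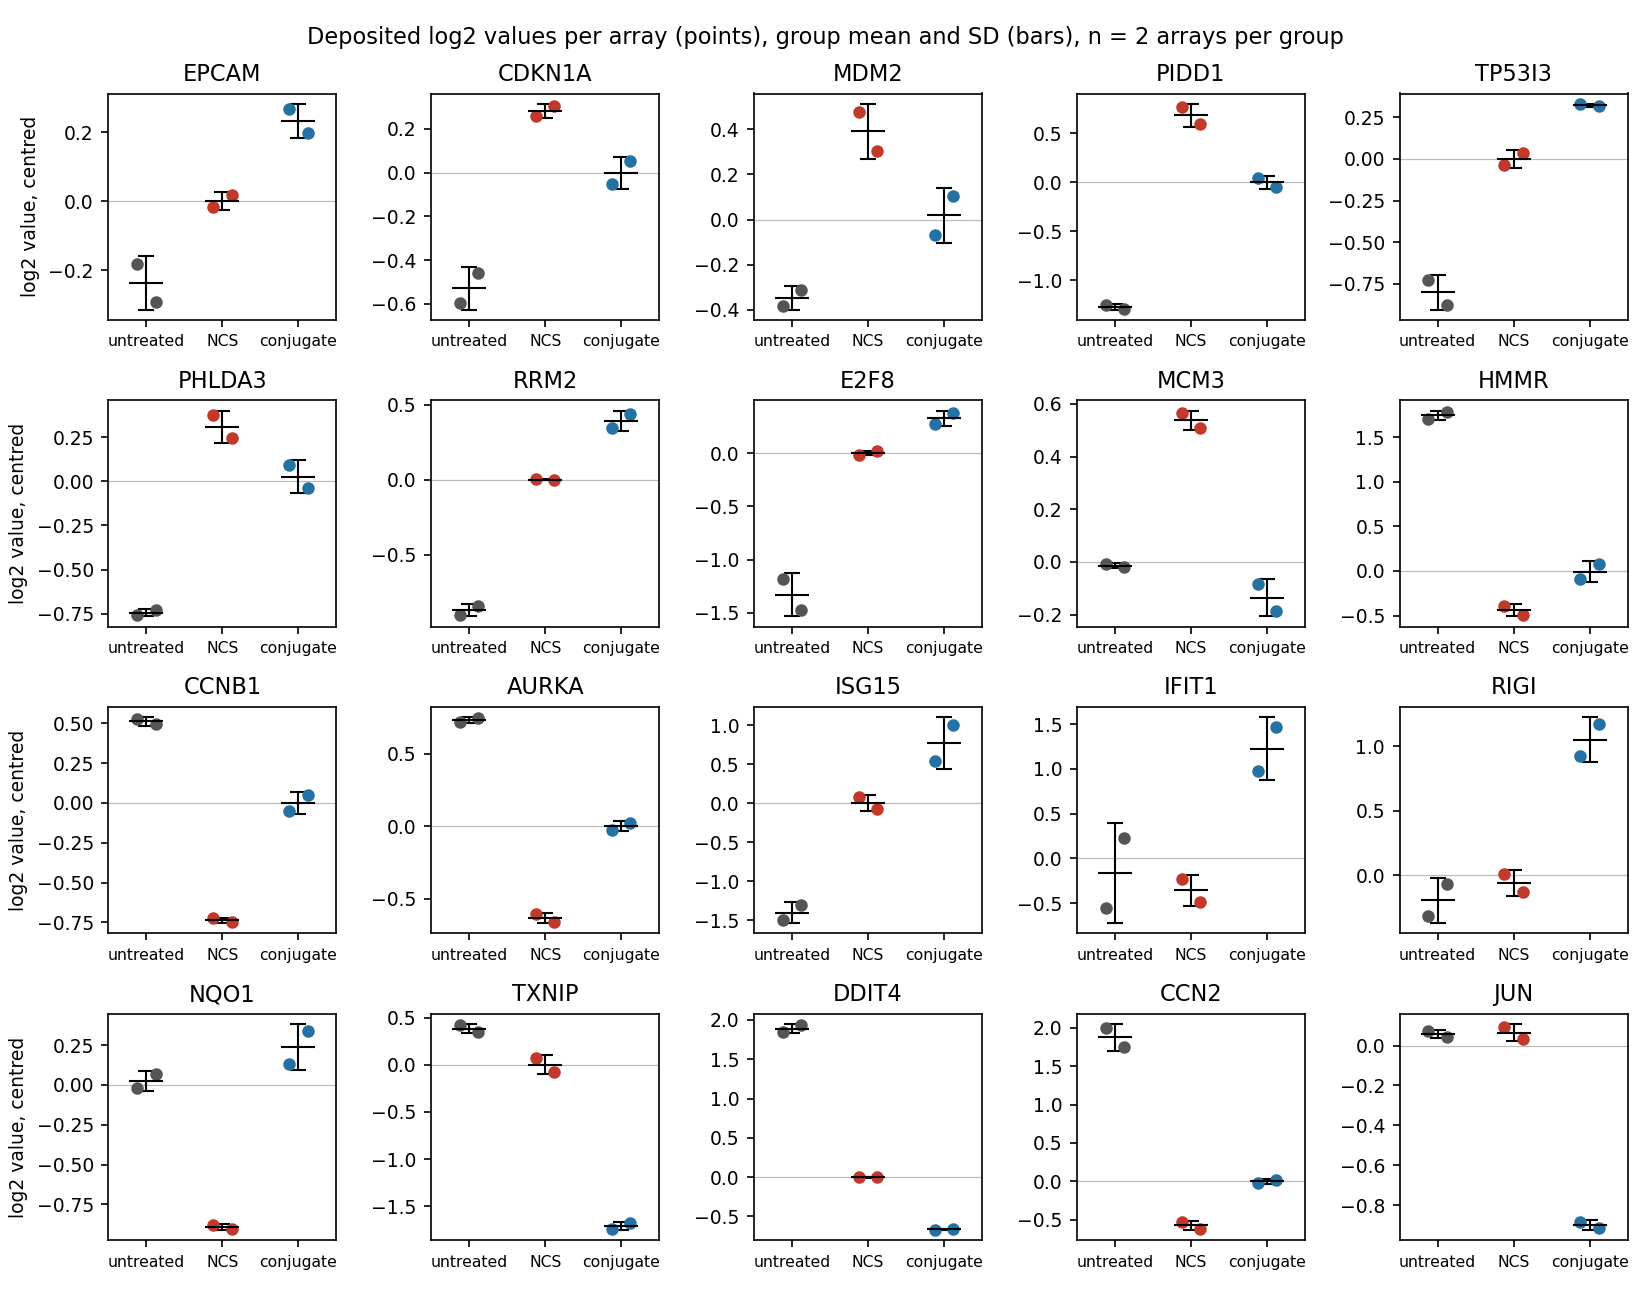
Deposited log2 values, centred on each probe set's median and averaged over a gene's probe sets, for 20 named genes; points are arrays, and bars are the group mean and SD of 2 arrays. MDM2 and PIDD1 are highest in the NCS arrays, IFIT1 and RIGI in the conjugate arrays, and TXNIP and JUN lowest in the conjugate arrays; under scaling on the hybridisation controls EPCAM and MDM2 were not higher in the conjugate than in untreated arrays.

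The last comparison sets the conjugate against free NCS directly, at the same time and unknown relative doses. Relative to other genes, camera with a preset correlation called mitotic, NRF2, oxidative phosphorylation and interferon lists higher and the ATF4 list lower in the conjugate samples, but 0 of these 5 list calls held with an estimated correlation, where 1 of 25 lists passed an unadjusted p under 0.05 and the lowest adjusted p = 0.549. Under scaling on the hybridisation controls the medians of the lists called higher, except the mitotic one, fell below 0. Relative to other genes, camera with the preset correlation still called 4 of the 5 lists there, but an equal shift of every gene bears little on that ranking. Single genes that were higher were IFIT1 (1.59 ± 0.24) and RIGI (1.10 ± 0.12), a cytosolic sensor of viral RNA, and TXNIP (-1.71 ± 0.09) was lower. limma called 1028 genes higher and 1117 lower in the conjugate samples, of which 13 and 61 differed at least 2-fold.

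In the G2/M and mitosis list, 12 of 39 measured members were called higher and 2 lower (16 and 3 when adjusted over the list alone). The G2/M list showed camera adjusted p = 0.000142, and adjusted p = 0.603 with an estimated correlation. The cyclin gene CCNB1 (0.74 ± 0.09), the spindle genes DLGAP5 (0.67 ± 0.10) and AURKA (0.63 ± 0.08) and ECT2 (0.62 ± 0.11), a factor of cytokinesis, were higher. CENPF (-0.53 ± 0.11) and AURKB (-0.33 ± 0.09), named after their values were seen, were lower. Scaling on the hybridisation controls left 0 higher and 0 lower by limma (4 and 3 at an unadjusted p under 0.05) with a list median of 0.030 against 0.20 in the deposited values. In the NRF2 list, 7 of 27 measured members were called higher and 0 lower (9 and 0 when adjusted over the list alone). The NRF2 list showed camera adjusted p = 0.000472, and adjusted p = 0.549 with an estimated correlation. Its median was 0.16 in the deposited values and -0.016 under that scaling, 0.16 above that of all genes, with 2 members called higher and 0 lower. NQO1 (1.13 ± 0.10), a quinone reductase, ME1 (0.95 ± 0.11), GCLM (0.76 ± 0.10), a subunit of the glutathione-making ligase, and HMOX1 (0.60 ± 0.10), heme oxygenase, were higher. Of the oxidative phosphorylation genes, 7 of 45 measured members were called higher and 0 lower (10 and 0 when adjusted over the list alone). The oxidative phosphorylation list showed camera adjusted p = 0.000559, and adjusted p = 0.603 with an estimated correlation. Their median was 0.15 in the deposited values and -0.026 under that scaling, 0.14 above that of all genes, with 0 members called higher and 0 lower by limma (3 and 1 at an unadjusted p under 0.05). The complex I genes NDUFB5 (0.70 ± 0.09), NDUFB3 (0.67 ± 0.11) and NDUFS1 (0.64 ± 0.09) and the complex II gene SDHD (0.52 ± 0.08) were among them. The members called higher in these 3 lists are lower in the NCS arrays, which have the lower GAPDH 5' minus 3' control, with means of -0.28 in NCS and 0.080 in conjugate arrays, and the higher Alu control (0.34 against -0.11) and 28S 5' control (0.71 against 0). Genes here that lost their call when 1 array was removed were ECT2 (0.0513 to 0.0565) without NCS 1 or conjugate 2, CENPF (0.0761 to 0.0928) without NCS 1, NCS 2 or conjugate 1, AURKB (0.0722 to 0.159) without any 1 of the 6 arrays.

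In the interferon list, 9 of 37 measured members were called higher and 1 lower (9 and 1 when adjusted over the list alone). The interferon list showed camera adjusted p = 0.0013, and adjusted p = 0.549 with an estimated correlation. The list median was 0.10 in the deposited values and -0.071 under scaling on the hybridisation controls, 0.10 above that of all genes, with 2 members called higher and 0 lower. IFIH1, another sensor of viral RNA, was higher by 0.83 ± 0.12 and IFI6 by 0.83 ± 0.13. The interferon gene IFNL1 (-0.42 ± 0.11), named after its value was seen, was lower. In the ATF4 list, 0 of 29 measured members were called higher and 3 lower (0 and 5 when adjusted over the list alone). The ATF4 list showed camera adjusted p = 0.0391, and adjusted p = 0.549 with an estimated correlation. The members called were DDIT4 (-0.67 ± 0.08), PDIA4 (-0.43 ± 0.09) and SLC7A5 (-0.40 ± 0.08). The ATF4 call ended under scaling on the hybridisation controls (adjusted p = 0.141), without NCS 1 (adjusted p = 0.09996) and without conjugate 2 (adjusted p = 0.149). EPCAM did not pass the test (0.23 ± 0.09, adjusted p = 0.125), nor did CDKN1A (-0.28 ± 0.09, adjusted p = 0.0813). MDM2 was called lower in the conjugate samples (-0.37 ± 0.10, adjusted p = 0.0446), but not under quantile normalization (adjusted p = 0.0663), with array weights (adjusted p = 0.0537), in a fit of the 2 groups (adjusted p = 0.0818) or under scaling on the hybridisation controls (adjusted p = 0.241). Its difference was larger, and called, without probe sets that can match several genes (-0.54, adjusted p = 0.019). With the highest-mean probe set it was -0.88 (adjusted p = 0.00703), but on centred values that rule picks by the differences between arrays. Removing 1 array ended these calls: IFNL1 (0.0772 to 0.222) without untreated 1, untreated 2, NCS 2, conjugate 1 or conjugate 2, PDIA4 (0.0596 to 0.0801) without NCS 1, NCS 2 or conjugate 1, SLC7A5 (0.0619 to 0.074) without NCS 1, NCS 2, conjugate 1 or conjugate 2, MDM2 (0.0656 to 0.195) without any 1 of the 6 arrays.

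The remaining 20 lists were not called. Of 31 p53 targets of arrest and feedback, 2 were called higher and 5 lower, 3 and 8 adjusted over the list alone (adjusted p = 0.328). Of 17 p53 targets of apoptosis, 2 were called higher and 3 lower, 3 and 3 adjusted over the list alone (adjusted p = 0.867). Of 10 apoptosis inhibitors, 1 was called higher and 0 lower, 2 and 1 adjusted over the list alone (adjusted p = 0.157). Of 43 S phase and replication genes, 5 were called higher and 10 lower, 8 and 12 adjusted over the list alone (adjusted p = 0.867). Of 45 replication-dependent histone genes, 2 were called higher and 0 lower (adjusted p = 0.156). Of 31 DNA double-strand break repair genes, 2 were called higher and 3 lower, 3 and 4 adjusted over the list alone (adjusted p = 0.907). Of 27 estrogen receptor targets, 0 were called higher and 3 lower (adjusted p = 0.356). Of 23 NF-kB and inflammatory genes, 0 were called higher and 0 lower (adjusted p = 0.907). Of 19 heat shock genes, 4 were called higher and 3 lower, 6 and 3 adjusted over the list alone (adjusted p = 0.328). Of 27 hypoxia and glycolysis genes, 2 were called higher and 1 lower (adjusted p = 0.919). Of 19 cholesterol synthesis genes, 3 were called higher and 0 lower (adjusted p = 0.498). Of 47 cytosolic ribosomal protein genes, 0 were called higher and 0 lower (adjusted p = 0.359). Of 27 luminal epithelial genes, 1 was called higher and 0 lower (adjusted p = 0.907). Of 24 basal and mesenchymal genes, 2 were called higher and 0 lower (adjusted p = 0.50). Of 18 EpCAM signalling and stemness genes, 2 were called higher and 1 lower (adjusted p = 0.895). Of 31 lysosome and autophagy genes, 6 were called higher and 2 lower, 10 and 5 adjusted over the list alone (adjusted p = 0.359). Of 29 immediate early and AP-1 genes, 1 was called higher and 1 lower, 1 and 3 adjusted over the list alone (adjusted p = 0.895). Of 16 fibroblast markers, 0 were called higher and 1 lower (adjusted p = 0.895). Of 17 leukocyte markers, 0 were called higher and 0 lower (adjusted p = 0.359). Of 12 endothelial markers, 0 were called higher and 1 lower (adjusted p = 0.359). Members that changed included the replication genes LIG1 (-1.14 ± 0.09) and MCM3 (-0.67 ± 0.09), the p53 targets SUSD6 (-0.82 ± 0.12) and PLK3 (-0.79 ± 0.09), JUN (-0.96 ± 0.08), a subunit of AP-1, and STC2 (-0.86 ± 0.09), which were lower. Higher were H1-2 (1.02 ± 0.10), DNAJA1 (0.64 ± 0.08), a co-chaperone, and KRT19 (0.56 ± 0.09), a keratin of luminal cells. Under scaling on the hybridisation controls 0 heat shock and 0 luminal epithelial genes were called higher. Of the 91 named genes called in this comparison, that scaling kept 38 calls and lost 53. The histone list was called without NCS 2 (adjusted p = 0.0458). Median, mean and test differed in sign for the S phase and replication genes (0.012, -0.042, downward), DNA double-strand break repair genes (0.023, -0.019, downward), hypoxia and glycolysis genes (-0.018, 0.0022, upward), immediate early and AP-1 genes (0.011, -0.016, downward) and fibroblast markers (0.00071, -0.019, downward).

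By size, the 10 highest genes of that kind were IFIT1, CYB5R4 (1.27 ± 0.10), CHAC2 (1.17 ± 0.13), a glutathione-degrading enzyme gene, KRTAP21-2 (1.15 ± 0.12), SCARNA14 (1.14 ± 0.25) and COMMD8 (1.13 ± 0.09), NQO1, RIGI and ZNF549 (1.08 ± 0.19) and SERTAD1 (1.03 ± 0.15). The 10 lowest were LINC01296 (-1.86 ± 0.12), POLR2J3 (-1.85 ± 0.13) and STAG3L2 (-1.80 ± 0.11), TXNIP, FBXW9 (-1.56 ± 0.15), NUP210 (-1.56 ± 0.13), a nuclear pore protein gene, PABPN1 (-1.50 ± 0.19), AP1G2 (-1.49 ± 0.11), AGAP5 (-1.47 ± 0.13) and CPNE7 (-1.46 ± 0.10). POLR2J3, STAG3L2 and AGAP5 belong to families with near-identical copies, which their probe sets may read together. The conjugate arrays were far apart for SCARNA14, at 0.43 and 1.45, against -0.17 and -0.23 in the NCS arrays. The 2145 called genes became 992 without NCS 1, 890 without NCS 2, 1089 without conjugate 1 and 913 without conjugate 2. Scaling on the hybridisation controls gave 24 genes higher and 415 lower. Calls that ended when an array was left out, with the adjusted p then found, were those of SCARNA14 (0.056 to 0.115) without untreated 1, untreated 2, NCS 1 or NCS 2, ZNF549 (0.0681) without NCS 2.

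Across genes, which are not independent replicates, the log2 fold changes of NCS and of the conjugate against untreated cells correlated with a Pearson r of 0.716 and a Spearman rho of 0.614. Both treatments share the same untreated arrays, and 50 simulations of unchanged treatments against them gave 0.499 and 0.473. The covariance was 0.0721 against 0.00735 in the simulations, an excess of 0.0648. With 2 untreated arrays the controls could not be split with replicates on each side, so part of the excess may still come from the shared controls. Called higher in both treatments were 704 genes, called lower in both 1360, and called in opposite directions 38. Independent calls would give 141 and 246 in the same direction, but calls against the same untreated arrays are not independent. The simulations of unchanged treatments had a mean of 0 genes called in the same direction in both. PIDD1, RIBC2, CGA and APOBEC3B were higher in both, and HMMR, CCN2, TSC22D3 and DDIT4 lower in both. In 713 genes the NCS samples were called higher than both other groups and in 658 lower, while the conjugate samples were called higher than both others in 222 genes and lower in 230. Each of these counts joins 2 comparisons that share the arrays of a group. Under scaling on the hybridisation controls the 4 counts became 93, 19, 4 and 264.

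**Figure D4:**
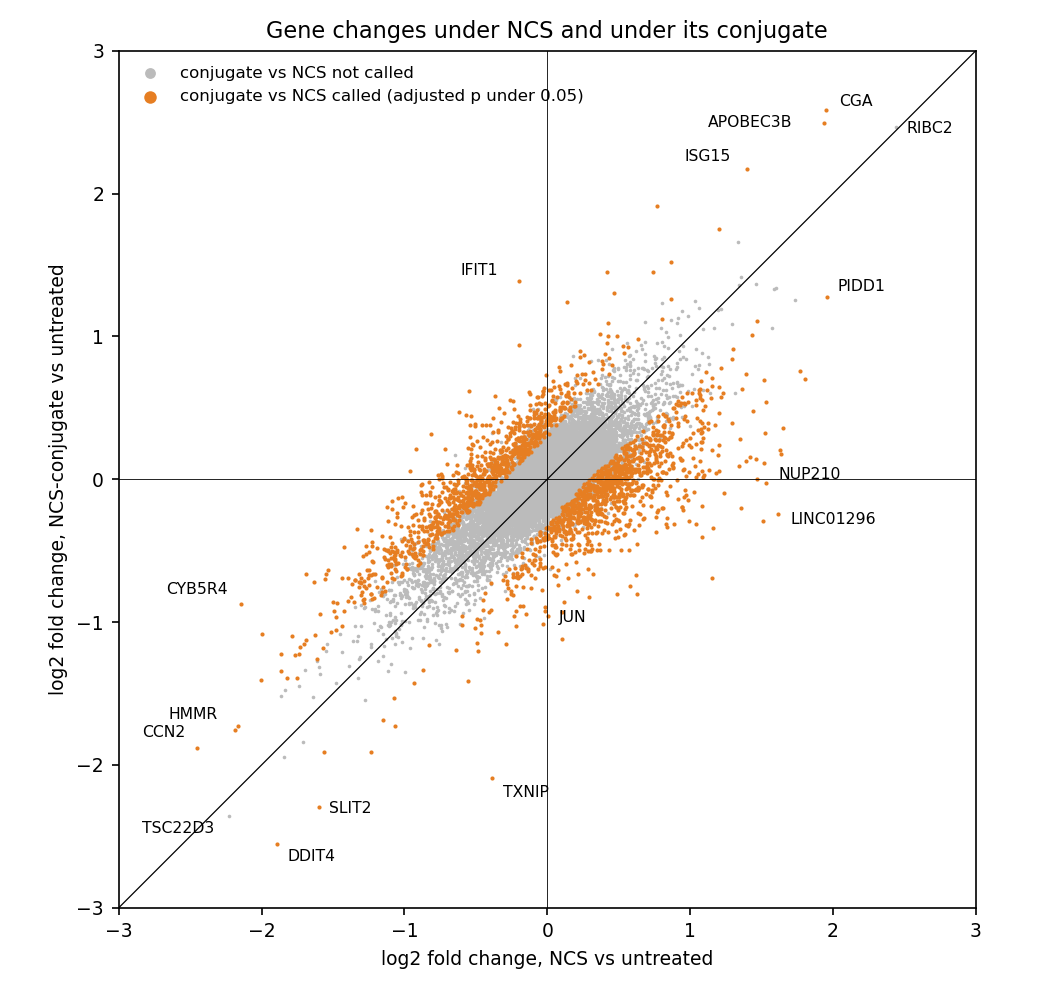
Log2 fold change of each gene under NCS (horizontal) and under the conjugate (vertical), each against the mean of the 2 untreated arrays; orange points are genes called between the treatments and the diagonal marks equal change. The points follow the diagonal (Pearson r 0.716), with IFIT1 above it and TXNIP and JUN below it; the untreated arrays are shared by both axes.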

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

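The tests of GC-dependent hybridisation, of RNA integrity, of leukocyte RNA and of a single array were chosen after the results were seen, and the test of nuclear RNA was written before its result.

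Compared directly, which tests the difference itself, the treatments differed in 5 gene lists by camera with a preset correlation, but in none of the 5 with an estimated one (adjusted p = 0.603 for G2/M and oxidative phosphorylation and adjusted p = 0.549 for the others). In that comparison 1 of 25 lists passed an unadjusted p under 0.05 with the estimated correlation, and fry called 6 in a direction, among them 4 of these 5 but not oxidative phosphorylation (adjusted p = 0.0795). The list median of conjugate minus NCS was 0.20 for G2/M genes, 0.10 for interferon genes, -0.077 for ATF4 genes, 0.16 for NRF2 genes and 0.15 for oxidative phosphorylation genes; under scaling on the hybridisation controls the interferon, NRF2 and oxidative phosphorylation medians turned to -0.071, -0.016 and -0.026.

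Probe sets outside the gene tests also moved. The Alu control was higher under NCS than in untreated cells by 0.34 (log2), the 28S rRNA 5' control by 1.63 and the 18S rRNA 3' control by 0.51, in 2 arrays of each group. Of 2473 probe sets without a gene name, 183 were called higher under NCS and 242 lower, and 82 were called higher under the conjugate and 162 lower.

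In 713 genes the NCS arrays were called higher than both other groups. For these genes, chosen by this difference, the NCS arrays lay a median of 0.59 and 0.54 above the mean of the other 4 arrays. GC-dependent hybridisation stays open: the GC slope of background controls was highest in NCS 2 (0.11 log2 per 10 steps of GC count), but that of NCS 1 (-0.015) lay among those of the other 4 arrays (-0.049 to 0.057), -0.071 from the highest of them. A larger part of nuclear or unspliced RNA cannot be told apart from a change in expression: 26 measured members of a fixed list of such RNAs had a median NCS minus conjugate difference of 0.13 (SD 0.37, 7 called higher and 1 lower). Their median NCS minus untreated difference was -0.046, with 6 called higher and 6 lower, so the list as a whole did not rise over untreated cells. Against the conjugate, camera placed the list higher in NCS at p = 0.0243 with the preset correlation, but p = 0.520 with an estimated one. Lower RNA integrity stays open too, because both NCS arrays lie below the other 4 in the GAPDH 5' minus 3' control by at least 0.29, while in the ACTB control the gap is -0.0016, an overlap. A true effect of free NCS, which the design names, also stays open and was not tested apart from these.

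In 9 interferon genes the conjugate was called higher than NCS, with a median difference of 0.77 and array medians, for genes chosen by this difference, of 0.54 and 0.71 in the conjugate and -0.059 and -0.074 in the NCS arrays. Lower RNA integrity under NCS stays open. The same genes stood 1.24 above untreated cells, whose integrity controls are the highest, so integrity alone would not give that rise. The pattern, however, is the gap between conjugate and NCS, and genes raised by both treatments could still read lower in the NCS arrays. Their median under NCS was 0.14 above untreated cells. A single conjugate array as the only source is argued against solely by the whole list of 37 measured members, which camera with the preset correlation still called without either conjugate array, at an adjusted p of at most 0.00244, although with an estimated correlation it was not called even with all arrays (adjusted p = 0.549). The values go against leukocyte RNA without excluding it. The 17 leukocyte markers differed by a median of 0.057, with 0 called higher by limma, 2 at an unadjusted p under 0.05, and the highest marker, CD68, at 0.32. This median is 0.0742 of the difference of the 9 genes, which were chosen by it, while the whole interferon list had a median of 0.10. Marker levels are unknown on centred values. Against untreated cells fry called the markers higher in the conjugate (adjusted p = 0.0367), and camera did not (adjusted p = 0.115). A candidate explanation is a response of the cells to the nucleic acid of the aptamer, but no arm received the aptamer or the linker alone, the doses are unknown, and this hypothesis was found on the same data and was not tested.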

How the results depend on the processing

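Alternatives chosen after seeing the data were the highest-mean probe set on centred values, leaving out probe sets that can match several genes, robust eBayes without trend, and scaling of the lists on the hybridisation controls. On centred values the highest-mean rule picks probe sets by the differences between arrays, so its results are no independent check. Counts are given for NCS against untreated, conjugate against untreated and conjugate against NCS, in that order, and stood at 4594, 3010 and 2145 called genes. Filters on dim genes and eBayes with trend, alone or with robust, were not run, because they need a signal level that the centred values lack. What signal over background limits can therefore not be assessed from this table.

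Within 1.5 times these counts were quantile normalization (3812, 2774 and 2042), median centring (4560, 3000 and 2155), robust eBayes (4573, 2988 and 2110), array weights (4685, 3197 and 1841), fits of the 2 groups compared (4600, 2850 and 1465), the replicate block (4372, 2737 and 1900), the highest-mean probe set (4133, 2523 and 1685) and probe sets that can match several genes left out (3606, 2295 and 1554). By their construction, stricter thresholds gave fewer: 379, 162 and 74 with at least a 2-fold change, 2808, 1374 and 665 at an adjusted p under 0.01 and 306, 85 and 10 with treat against a fold of 1.5. An adjusted p under 0.10 gave 5730, 4132 and 3262. Testing every probe set on its own gave 9293, 5619 and 4260 probe sets, as more were tested. Of 340 named results, 316 kept their direction and side of the threshold under quantile normalization, 335 under median centring, 336 with array weights, 340 with robust eBayes, 323 in fits of 2 groups and 276 with the highest-mean probe set. Without probe sets that can match several genes 265 did, 17 lost their call, ACTA2 turned and the others had no probe set left.

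Under scaling on the hybridisation controls 2842, 6176 and 439 genes were called, by its construction, since it moves the median of all genes. The conjugate arrays' own controls differ (-0.0073 and 0.46), which widens the spread. Among 340 named results it left 224 on the same side of the threshold, 101 were no longer called and 1 was gained. Another 14 turned and likewise lost their call, with a lowest limma adjusted p = 0.438, for RPS9. Directions turned under it for COX7B (-0.040), NDUFV1 (-0.0024), SDHA (-0.017) and SLC7A5 (-0.054) in NCS against untreated, and for ACTA2 (-0.11), CD68 (-0.13), EPCAM (-0.023), MDM2 (-0.13) and OLFM1 (-0.045), PMVK (-0.066), RPL32 (-0.051), RPS14 (-0.052), RPS9 (-0.19) and TNFAIP3 (-0.13) in conjugate against untreated. With the highest-mean probe set CD44 (-0.12) turned in the first comparison, ACTA2 (-0.049) and CTNNB1 (0.21) in the next and ATG5 (-0.11) in the last, and ACTA2 also turned without probe sets that can match several genes (-0.037). None of the values that turned, under scaling or with other probe sets, was called. The turns under scaling follow from its equal shift of every gene. For the turns with other probe sets the cause was not tested.

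Leaving out 1 array, with the lone array of its group assumed to vary like the other groups, gave 2796 to 4600 called genes for NCS against untreated, lowest without untreated 1 and at 2846 without untreated 2. For the conjugate against untreated the range was 1189 to 2850, lowest without untreated 1, with 1467 without untreated 2, 1954 without conjugate 1 and 1840 without conjugate 2. For the conjugate against NCS it was 890 to 1465, lowest without NCS 2, with 992 without NCS 1, 1089 without conjugate 1 and 913 without conjugate 2. Counts were lower where the array left out belonged to a group compared than where it belonged to the third group, and the cause was not tested. Named results on the same side of the threshold numbered 275 to 294 of 340, and 0 turned. The correlation of the treatments, 0.716, ranged from 0.676 without conjugate 1 to 0.732 without untreated 2.

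The list calls depend on the test. Camera with the preset correlation called 10, 8 and 5 of 25 lists, and 0, 0 and 0 with an estimated correlation, where 6, 5 and 1 passed an unadjusted p under 0.05 and the lowest adjusted p = 0.192, 0.135 and 0.549. With 3 residual degrees of freedom that correlation is itself poorly estimated. Fry, which tests a list on its own and not against other genes, called 18, 11 and 6 lists in a direction and 24, 25 and 24 in either direction. With camera, scaling on the hybridisation controls gave 11, 10 and 4 lists, leaving out probe sets that can match several genes 7, 8 and 5, and leaving out 1 array 10 to 11, 8 to 9 and 4 to 6. Of the 10, 8 and 5 main list calls, 10, 8 and 4 were kept under scaling on the hybridisation controls. Camera ranks a list against other genes, so these calls could hardly respond to an equal shift of every gene. The replicate block added the histone list under NCS (adjusted p = 0.0389) and heat shock under the conjugate (adjusted p = 0.0424), and ended the ATF4 call between treatments (adjusted p = 0.0536). It also ended the MDM2 calls of the conjugate against untreated cells (adjusted p = 0.0543) and against NCS (adjusted p = 0.0627). Among all named results the block left 327 on the same side of the threshold, 12 lost their call and 1 was gained.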

Other observations

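The genes and probe sets in this part were chosen after their values were seen. The conjugate was called apart from both other groups in 222 genes that were higher and 230 that were lower. Among the higher ones, with the log2 difference from untreated cells and then from NCS, were DBR1 (0.73, 0.74), the enzyme that opens RNA lariats, and SERTAD1 (1.45, 1.03), a regulator of CDK4 and E2F. Among the lower ones were CLK2 (-1.01, -0.99), a kinase of splicing factors, JUN (-0.96, -0.96), APP (-0.93, -1.04), the amyloid precursor protein gene, ADAMTS17 (-0.92, -0.91), a secreted protease gene, and ND4 (-0.89, -0.87), a mitochondrially coded subunit of complex I. NCS minus untreated values of JUN, CLK2 and ND4 were not called (0.0074, -0.027 and -0.017).

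For genes in which free NCS was called apart from both other groups, the values are NCS and then conjugate minus untreated. Higher were LINC01296 (1.61, -0.24), a long non-coding RNA, and NUP210 (1.53, -0.026), a nuclear pore protein gene. So were GPAA1 (1.63, 0.21), a gene of GPI anchor attachment, and CCNT1 (1.52, 0.12), the cyclin of P-TEFb. Lower than both others were CYB5R4 (-2.14, -0.88), a reductase gene, OIP5 (-0.96, 0.055), a factor of centromere assembly, ME1 (-1.43, -0.48) and NQO1 (-0.92, 0.21), and CAPZA2 (-1.63, -0.72), an actin capping protein gene. Under the conjugate CYB5R4, ME1 and CAPZA2 also stood below untreated cells. Some of the genes higher under NCS than in both other groups, such as AGAP5 (1.47, 0.00062) and SPDYE2B (1.46, 0.14), belong to families with near-identical copies.

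Of the 2473 probe sets without a gene name, some fell under NCS by more than any gene named here. Single probe sets with a gene name were not ranked against them. One probe set stood at 6.81 and 6.86 in the untreated arrays and changed by -6.93 under NCS and -6.91 under the conjugate. Another stood at 6.61 and 6.55 and changed by -6.58 and -6.67. The files do not pair them with a gene.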
